A study of Mus musculus with 4 samples.

How the data were processed

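Gene expression was measured on 4 Affymetrix arrays, each hybridised with biotin-labelled material prepared from total RNA. The RNA came from mouse dendritic cells (DCs) grown from bone marrow with Flt3 ligand (200 ng/ml) for 8 days. The deposited labels name a genotype, miR-142 wild type (wt) or knockout (ko), and a sorted subset, CD4-equivalent or CD8-equivalent DCs, so each of the groups holds 1 array. The labels do not say how many mice or cultures stand behind an array, nor whether both subsets of a genotype came from the same culture. The number of arrays limits the precision of every value.

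The deposited values are log2 expression summaries, 1 per probe set and array. The submitters' processing notes name RMA and Partek, and the labels give the standard Affymetrix labelling protocol. RMA corrects background, quantile-normalises arrays together and summarises the probes of each set on the log2 scale. The log base is not stated and was inferred from the values, which run from 3.52 to 14.3. Software versions, the annotation behind the probe sets and any later step are not given in the sources used here. No scanner values were used here, so the scale and centring of the values could not be set against them. The column medians were 5.91 for wt CD4-equivalent, 5.87 for wt CD8-equivalent, 5.88 for ko CD4-equivalent and 5.94 for ko CD8-equivalent DCs. No detection calls were used, and RMA compresses differences at the low end of its range, so a difference from a value near background understates or blurs the true ratio.

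Of 35399 probe sets, 21789 carried 1 gene symbol in the platform annotation of 2016, 1621 carried several and 11989 were unnamed here. Of the probe sets with 1 symbol, 21698 matched a RefSeq gene of the GRCm38.p6 assembly by gene ID, and 0 symbols changed by that match. Only probe sets with 1 symbol entered the comparisons, which gave 19938 genes. For the 999 genes with several probe sets, the probe set with the highest mean over the arrays was used. The array annotation names no assembly that could be matched, so no coordinates are given, and RefSeq served only for names and for the order of neighbouring genes.

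For each pairwise comparison the difference of the log2 values of 2 arrays was taken, with no test and no p-value. A gene was compared when the higher of its 2 values reached the floor of 5.68, the median of all single-gene probe sets over the arrays, and it was counted as differing at 2-fold or more, a log2 difference of 1. Effects common to both subsets or both genotypes were tested with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on an additive model of genotype and subset over 10239 genes that reached the floor on any array. The test was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This model has 1 residual degree of freedom, the genotype by subset interaction, plus 3.98 prior degrees of freedom that limma estimated across genes. It treats the subsets as replicates of the genotype difference and the genotypes as replicates of the subset difference, so its p-values measure only the spread between these arrays, which may be technical. The interaction takes the last degree of freedom and was given as a value without a test. On simulated data for the genotype comparison over 10239 genes, 89 of 100 genes changed by a log2 difference of 1 and 100 of 100 changed by 2 were recovered with the right sign, with 18 false calls among 207 calls. The adjustment is looser with that many calls than in the real genotype fit, which made 17, so these recovery rates do not carry over to it. There the gene Cfl2, with a mean difference of 1.31, was not called, and an uncalled gene may still differ.

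Gene lists of 24 kinds were written from textbook knowledge. They covered markers of CD8-equivalent DCs (cDC1), CD4-equivalent DCs (cDC2), plasmacytoid DCs, monocytes and macrophages, neutrophils, B cells, T and NK cells, erythroid and megakaryocyte cells, mast cells with basophils and eosinophils, and stem and progenitor cells. Others held DC maturation genes, MHC class II presentation, MHC class I presentation, interferon-stimulated genes, inflammatory cytokines with NF-kB feedback genes, reported miR-142 targets, the Notch and lymphotoxin pathway, DC growth factor receptors with transcription factors, cell cycle genes, immediate-early and stress genes, apoptosis regulators, cholesterol synthesis, glycolysis, and actin and migration genes. A further list of sex-linked genes served as a sample check. For each list, the median difference over its measured members was set against 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these arrays. Members at or above the floor were counted as at least 2-fold higher, at least 2-fold lower or under 2-fold, and limma's p-values were also adjusted over the list alone. Over the 96 combinations of list and pairwise comparison, 51 medians lay outside the central 95% of random lists, where 4.8 would if list members varied independently. Members of a list are often expressed together, the comparisons share arrays, and some lists hold markers of the sorted subsets. The excess over 4.8 is therefore no measure of evidence.

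The genes named were the 10 highest and 10 lowest of each pairwise comparison, the 10 highest and 10 lowest of those that differed the same way in both subsets, ranked by the smaller difference, the 5 highest and 5 lowest of the interaction, and members of the lists, with Mir142 and the sort markers always given. The values of 1 list member are not reported here. Predicted genes, Riken names, olfactory and vomeronasal receptors, small RNA genes and antigen receptor segments were counted but not named by rank. Groups, tests, lists, the naming rule and the alternatives below were fixed before the data were examined, except where the text says otherwise.

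The alternatives were no floor, a stricter floor at the upper quartile, thresholds of 1.5-fold and 3-fold, an adjusted p of 0.1, limma's trended and robust variance prior, repeated quantile normalisation, cyclic loess, the mean of a gene's probe sets, unmatched random lists, list members above the floor, and marker lists without the sort markers. After the data were seen, a count without the neutrophil and plasmacytoid lists and a check without the CD4-equivalent arrays were added. A planned search for miR-142 seed matches in 3' UTRs was left out because no genome sequence was used here. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9, and the adjustment over a list alone with statsmodels 0.14.6.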

Results

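Dendritic cells (DCs) were grown from the bone marrow of C57BL/6 mice with intact miR-142 (wt) or without it (ko), in Flt3 ligand, the cytokine that supports conventional and plasmacytoid DCs. miR-142 is a microRNA found across blood cell lineages. Sorting excluded B220-positive cells and split CD11c-positive cells into CD4-equivalent DCs, which carry CD172a and CD11b, and CD8-equivalent DCs, which carry CD24. Each of the 4 groups was measured on 1 array as RMA log2 values, and 9774 to 9821 of 19938 genes reached the floor of 5.68 on an array. There are no replicates, so differences between single arrays have no replicate check and no p-value. The study compared the genotypes within each subset, and the design also allows the subsets to be compared within each genotype.

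Mir142, the gene of the deleted microRNA, was examined first in every sample. Its probe set (10380135, chromosome 11) read 10.37 in wt CD4-equivalent and 9.87 in wt CD8-equivalent DCs, against 4.92 and 4.79 in the corresponding ko arrays. These levels were 43.7-fold and 33.8-fold lower in ko and lay below the floor. The labels do not say which part of the locus was removed, so the probe set checks the genotype labels only if it lies in that part. The genes of the sort markers followed the subset labels in both genotypes. Sirpa, which encodes CD172a, was 5.36-fold lower in CD8-equivalent than in CD4-equivalent DCs of wt and 4.75-fold lower in ko, and Itgam, which encodes CD11b, was 4.01-fold and 3.66-fold lower. Cd24a was 3.43-fold higher in CD8-equivalent DCs of wt and 1.66-fold higher in ko. Itgax, which encodes CD11c and was used for both gates, differed by 0.52 and 0.18 on the log2 scale. Among the sex-linked check genes, the Y-linked Kdm5d (8.52 to 8.84), Eif2s3y (9.76 to 10.47) and Uty (8.82 to 9.10) were expressed on all 4 arrays, while Xist stayed at 4.43 to 4.63.

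The first question was which genes differed between ko and wt whatever the subset. Besides Mir142 (mean log2 difference -5.26 ± 0.14 (SE), adjusted p = 0.0029), the most significant gene was Rnf43, a ubiquitin ligase that removes Wnt receptors from the cell surface. Rnf43 rose by 3.71 in CD4-equivalent and 3.67 in CD8-equivalent DCs (adjusted p = 0.0031). Hoxa9, a homeobox transcription factor of haematopoietic progenitors, rose by 3.46 and 3.02, and Eya1, a transcriptional coactivator and phosphatase of developing organs, by 3.61 and 3.12 (adjusted p = 0.0095 for both). Igf2bp3, an RNA-binding protein of fetal haematopoietic cells, rose by 1.52 and 1.79 (adjusted p = 0.041), and Abca1, the cholesterol efflux pump, by 1.68 and 1.93 (adjusted p = 0.032). Among the genes that fell were the orphan receptor Gpr82 (-2.87 and -2.98, adjusted p = 0.0071), the lactosylceramide synthase B4galt6 (-2.26 and -2.45, adjusted p = 0.013) and the prostaglandin E2 receptor Ptger3 (-2.74 and -2.37, adjusted p = 0.015). Ahrr, which represses the aryl hydrocarbon receptor, changed by -2.39 and -2.04 (adjusted p = 0.025), and the water and glycerol channel Aqp9 by -1.53 and -1.70 (adjusted p = 0.035).

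In all, limma with Benjamini-Hochberg adjustment called 17 of 10239 genes for genotype, 11 higher and 6 lower in ko, each in the same direction in both subsets. At an unadjusted p under 0.05 there were 752 higher and 847 lower genes. The remaining called genes were all higher in ko: Tmem119 (1.97 and 1.80), the muscarinic receptor gene Chrm3 (2.20 and 1.83), the kallikrein-related genes Klk1b27 (1.59 and 1.77) and Klk1b11 (3.17 and 2.28), the tetraspanin gene Cd151 (1.40 and 1.41) and the sphingosine-1-phosphate receptor gene S1pr3 (1.43 and 1.71). Their adjusted p-values ran from 0.025 to 0.046. The Klk1b genes are near-identical paralogs whose probes may be shared, so their values are uncertain, and Cd151 and S1pr3 fall outside the naming rule and were chosen after their values were seen. Other genes that differed by at least 2-fold the same way in both subsets did not pass the test, such as the granule enzyme myeloperoxidase (Mpo, 1.85 and 2.76, adjusted p = 0.053), the solute carrier Slc16a14 (-3.28 and -2.24, adjusted p = 0.053), the antiviral membrane protein Ifitm1 (-1.71 and -3.31, adjusted p = 0.079), Ms4a4a (-2.17 and -1.53, adjusted p = 0.053) and the metalloelastase Mmp12 (-1.52 and -1.99, adjusted p = 0.050). The number of calls depended on the settings: it was 3 without the floor and 307 with limma's trended and robust prior.

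**Figure D1:**
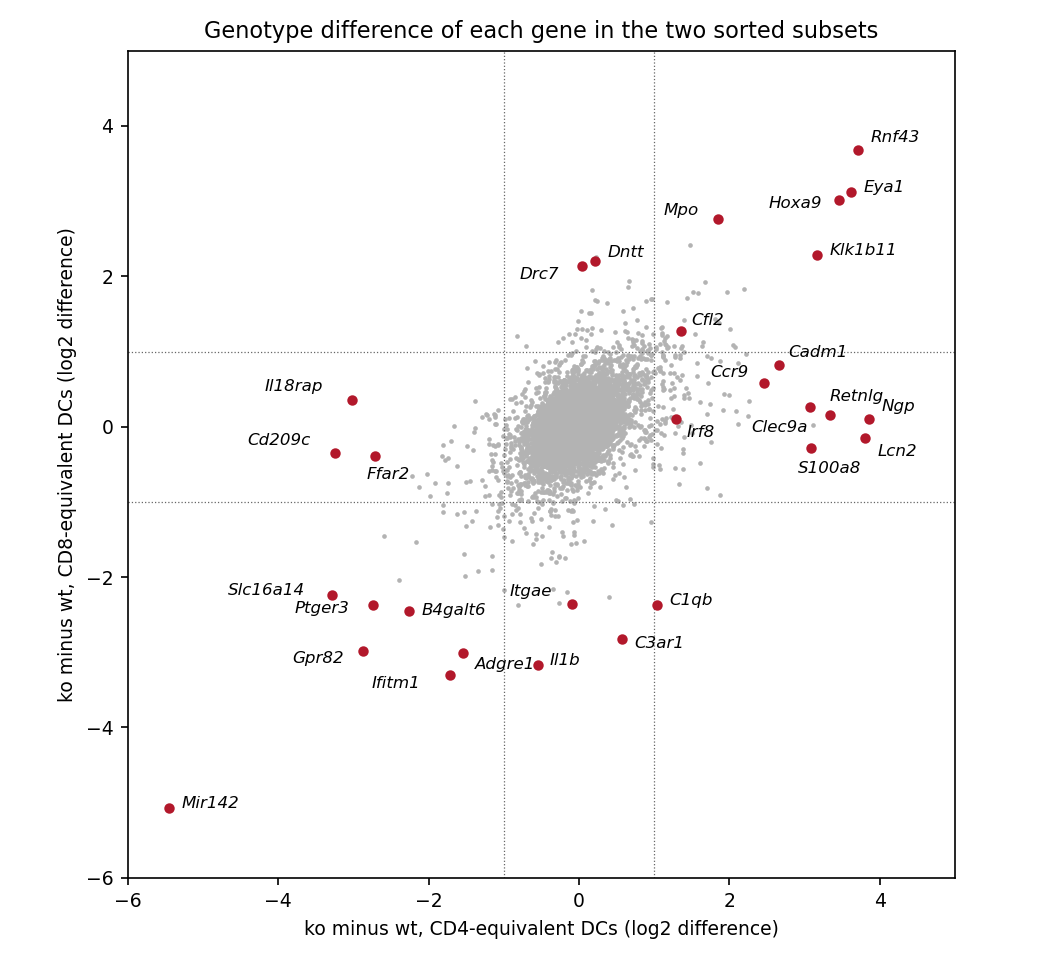
Log2 difference between ko and wt for each gene at or above the floor, in CD4-equivalent DCs on the horizontal axis and CD8-equivalent DCs on the vertical axis, with named genes in red and dotted lines at a 2-fold difference. Mir142 lies at -5.45 and -5.08, Rnf43, Eya1 and Hoxa9 lie above 3 on both axes, and the granulocyte genes Ngp and Lcn2 lie far from 0 on the horizontal axis alone.

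The genotype differences of the subsets, which share no array, were correlated across 10239 genes (Pearson r = 0.49, Spearman correlation 0.39), though genes are not independent replicates. At 2-fold or more, 40 genes were higher in ko in both subsets and 31 were lower in both, where independent lists would share 1.55 and 0.937. Only C1qb, a complement component of macrophages, passed 2-fold in opposite directions, though C1qc came close (0.96 and -1.26). In the RefSeq order of genes, Rnf43 is the measured neighbour of Mir142 on one side, and Tspoap1 and Mpo follow it on the other. Tspoap1 (-0.50 and -0.85) lay below the floor on all 4 arrays, so its differences are not informative.

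Genes reported as miR-142 targets were mostly higher in ko. Of 18 such genes at or above the floor, 16 had a higher value in ko in CD4-equivalent DCs and 16 in CD8-equivalent DCs. In each subset 3 were at least 2-fold higher, 0 at least 2-fold lower and 15 under 2-fold. The count of higher values includes differences near 0, such as Rac1 (0.018 and 0.006) and Sirt1 (0.012 and 0.034). For comparison, the median of all genes compared was -0.08 in CD4-equivalent and 0.004 in CD8-equivalent DCs. The actin regulator Cfl2 was higher by 1.36 and 1.27, the TGF-beta receptor gene Tgfbr1 by 1.39 and 0.99, the actin nucleation factor Wasl by 0.83 and 1.14, and the actin-binding Twf1 by 0.75 and 0.80. With limma, 5 targets rose when adjusted over the list alone (among them Tgfbr1, Wasl, Cfl2 and Twf1) and 0 over all genes tested. The median of the 21 measured targets was 0.04 in CD4-equivalent DCs, at percentile 95.8 of matched random lists, and 0.28 in CD8-equivalent DCs, at percentile 100. In CD4-equivalent DCs it was 0.16 after cyclic loess (percentile 99.8) and over the members above the floor (percentile 99.9).

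Interferon-stimulated genes were lower in ko in both subsets. All 23 measured members lay below wt in CD4-equivalent DCs, 5 of them by at least 2-fold, and the median was -0.76, at percentile 0 of matched random lists. The exonuclease gene Isg20 (-1.81), the chaperone gene Rtp4 (-1.75) and the 2'-5' oligoadenylate synthetase gene Oas1a (-1.38) stood lowest. In CD8-equivalent DCs 12 of 15 members at or above the floor were lower, 2 by at least 2-fold (Isg20 with -1.05 and the RIG-I-like receptor Dhx58 with -1.03), with a median of -0.34 over all 23 members at percentile 0. The other 8 members lay below the floor on both CD8-equivalent arrays and could not show a fall, so the medians of the subsets are not comparable in size. The list also stood lower in CD8-equivalent than in CD4-equivalent DCs of wt (median -1.83), and the ko CD4-equivalent array carried higher neutrophil (median 1.63) and plasmacytoid (0.65) markers. Whether the mix of sorted cells bears on the fall in CD4-equivalent DCs was not tested. With limma, 13 members fell when adjusted over the list alone, among them Ddx58, which encodes RIG-I (-0.92 and -0.91), Usp18 (-0.91 and -0.75), Mx1 (-0.51 and -0.44) and Stat2 (-0.45 and -0.38), and 0 over all genes tested.

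In CD4-equivalent DCs, ko minus wt, the secondary granule genes Ngp (3.86) and Lcn2 (3.80) of granulocytes had the largest positive differences, followed by Rnf43, Eya1 and Hoxa9. Other granulocyte genes, the resistin-like Retnlg (3.33) and the calprotectin genes S100a9 (3.11) and S100a8 (3.08), were also among the 10 highest, and these 5 granulocyte genes were 8.47-fold to 14.5-fold higher in ko. Among the lowest were the proton-coupled transporter relative Slc16a14, the C-type lectin Cd209c (-3.25), the IL-18 receptor subunit Il18rap (-3.02), the short-chain fatty acid receptor Ffar2 (-2.72), Tmem154 (-2.60) and the pseudogene Nlrp1c-ps (-2.23). Of 9978 genes compared, 139 were at least 2-fold higher in ko and 95 at least 2-fold lower. After cyclic loess the share of higher genes among them was 69.7%, against 59.4% as deposited.

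Of 12 neutrophil markers at or above the floor, 10 were at least 2-fold higher in ko CD4-equivalent DCs and 0 lower, with a median of 1.63 over 14 measured members (percentile 100). Camp, another secondary granule gene, read 5.10 in ko and 4.88 in wt, below the floor. Of 11 plasmacytoid DC markers, 10 lay above 0, with a median of 0.65 (percentile 100) over the measured members. The chemokine receptor Ccr9 (2.47), the lectin Siglech (1.40) and the cytochrome oxidase subunit Cox6a2 (1.10) were the 3 at least 2-fold higher. Ly6d (0.14) and Irf7 (-0.26), which is also on the interferon list, were under 2-fold. Of 18 CD8-equivalent markers, 5 were at least 2-fold higher and 0 lower. These were the dead-cell receptor Clec9a (3.07), the adhesion molecule Cadm1 (2.67), the profilin receptor Tlr12 (1.60), the DC transcription factor Irf8 (1.29) and Cd24a (1.00), but 9 of the 18 lay below 0. The list's median was 0.06 (percentile 98.4) over its 25 measured members, but -0.012 (percentile 77.7) over the members above the floor and at percentile 90.2 after cyclic loess. Of 21 CD4-equivalent markers, the lectin Mgl2 was higher (1.13), and 3 were at least 2-fold lower, the inhibitory lectin Clec4a4 (-1.80), the cytokine Ltb (-1.19) and Clec4a2 (-1.09), with a median of 0.05 (percentile 97.7, and 92.9 after cyclic loess). Monocyte and macrophage markers had a median of 0.03 (percentile 84.2), but 0.22 (percentile 99.9) over the members above the floor, with Chil3 (1.28) and C1qb (1.03) higher and Adgre1, which encodes F4/80, lower (-1.55).

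**Figure D2:**
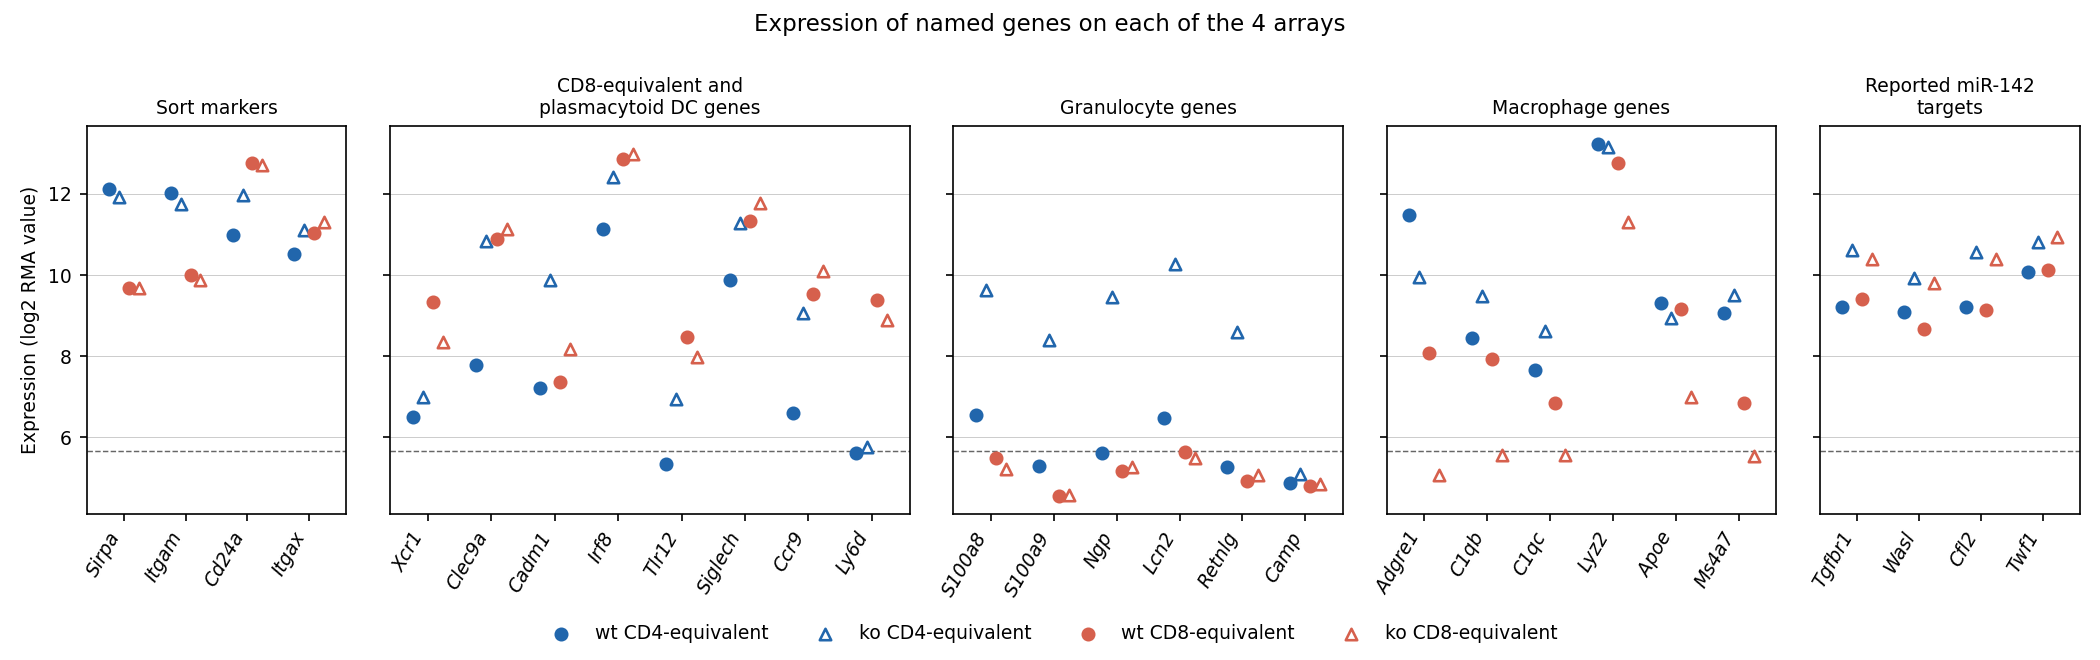
RMA log2 expression of named genes on each of the 4 arrays, with wt as filled circles, ko as open triangles, CD4-equivalent DCs in blue, CD8-equivalent DCs in red and the floor as a dashed line. Each symbol is 1 array, and S100a8, S100a9, Ngp, Lcn2 and Retnlg stand above 8 only on the ko CD4-equivalent array.

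In CD8-equivalent DCs, ko minus wt, macrophage genes were lower, and Mpo and Dntt, enzymes of myeloid and lymphoid progenitors, were higher. Ifitm1 (-3.31), the cytokine Il1b (-3.16), the F4/80 gene Adgre1 (-3.00), the complement receptor C3ar1 (-2.83), C1qb (-2.37), the lectin Clec4a1 (-2.37) and the integrin Itgae (-2.36), which encodes CD103, were among the lowest. After Rnf43, Eya1 and Hoxa9, the highest were Mpo (2.76), the microtubule-associated ligase Mid1 (2.41), Klk1b11 (2.28), the coagulation factor F13a1 (2.26), the terminal deoxynucleotidyl transferase Dntt (2.20), the ciliary gene Drc7 (2.13) and Tmem176a (1.94). Of 9972 genes compared, 114 were at least 2-fold higher and 100 at least 2-fold lower in ko.

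Of 11 monocyte and macrophage markers at or above the floor in CD8-equivalent DCs, 6 were at least 2-fold lower in ko and 0 higher, with a median of -0.32 over 18 measured members (percentile 0). Besides Adgre1 and C1qb these were the lipoprotein gene Apoe (-2.16), lysozyme Lyz2 (-1.44), Ms4a7 (-1.31) and C1qc (-1.26). Of 21 CD8-equivalent markers, 18 lay below 0 and 4 were at least 2-fold lower, Itgae, Hepacam2 (-1.52), the scavenger receptor Cd36 (-1.27) and Rab32 (-1.01), with a median of -0.33 (percentile 0). Xcr1, the chemokine receptor typical of these cells, read 9.33 in wt and 8.36 in ko, and Clec9a and Irf8 differed by 0.26 and 0.11. The neutrophil list had a median of 0.04 (percentile 69.0), and Mpo was its only member at least 2-fold higher among 2 at or above the floor. Plasmacytoid markers had a median of 0.08 (percentile 86.9) and CD4-equivalent markers -0.04 (percentile 25.2), where Clec4a2 (-1.20) alone passed 2-fold. In limma's genotype test of these marker lists, 0 members were called over all genes tested. Adjusted over the list alone, Hepacam2 and Cd36 fell among CD8-equivalent markers, Cx3cr1 and Mgl2 rose and Clec4a2 and Ltb fell among CD4-equivalent markers, Adgre1 fell among macrophage markers, and Mpo rose and Mmp8 fell among neutrophil markers.

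The remaining lists varied in how far the genotypes differed. DC maturation genes had medians of 0.006 (percentile 82.8) in CD4-equivalent and -0.15 (percentile 0.4) in CD8-equivalent DCs, and the costimulatory ligand Cd86 was lower in ko in both (-1.37 and -1.12). Adjusted over the list alone, Cd80, Cd86 and Birc3 fell and the chemokine receptor Ccr7 rose. MHC class II genes had medians of -0.09 (percentile 16.6) and -0.24 (percentile 0.4), with the transactivator Ciita lower by list-alone adjustment (-0.52 and -0.61), and MHC class I genes 0.04 (percentile 90.9) and -0.18 (percentile 2.65, but 1.93 after cyclic loess and 0.23 among unmatched lists). Cell cycle genes had medians of 0.27 and 0.25 (percentile 100 in both), with 15 and 24 of 25 members above 0, but 0 reached 2-fold and 0 were called by limma over the list alone. The 10 members below 0 in CD4-equivalent DCs were mostly replication genes, such as the helicase gene Mcm4 (-0.54) and the thymidylate synthase gene Tyms (-0.30). Stem and progenitor markers had medians of 0.06 (percentile 91.6) and 0.32 (percentile 99.9), and the progenitor transcription factors Myb (1.11 and 0.94) and Meis1 (0.95 and 1.70) rose when adjusted over the list alone. Immediate-early and stress genes had medians of 0.24 (percentile 99.98) in CD4-equivalent and -0.33 (percentile 0.02) in CD8-equivalent DCs, where Atf3 (-1.41) was lowest. Within this list Egr1 and Egr3 rose and Ier3 fell in both subsets when adjusted over the list alone. Over all genes tested, limma's genotype test called 0 members of any list of this paragraph.

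Inflammatory cytokines had medians of 0.04 (percentile 82.0) and -0.06 (percentile 6.89), and Il12a (0.65 and 1.19) and Ccl3 (0.69 and 0.95) rose by list-alone adjustment. Notch and lymphotoxin genes had medians of 0.05 (percentile 92.8) and 0.04 (percentile 80.3), with Ltb lower over the list alone. DC growth factor receptors and transcription factors had medians of 0.04 (percentile 98.4, and 95.2 after cyclic loess) and -0.15 (percentile 0.39), with the cytokine receptor Csf2rb lower in CD8-equivalent DCs (-1.08) and Flt3 itself differing by -0.29 and 0.16. Cholesterol synthesis genes stood at 0.16 (percentile 99.8) and -0.07 (percentile 24.9). Apoptosis regulators (-0.03 at percentile 70.4 and -0.02 at percentile 43.6), glycolysis genes (-0.02 at percentile 66.3 and -0.03 at percentile 47.8) and actin and migration genes (-0.05 at percentile 36.0 and -0.003 at percentile 73.9) lay inside the central 95% of random lists, though Wasl, Cfl2 and Twf1, shared with the target list, rose over the actin list alone. Of other lineages, B cell markers had medians of -0.02 (percentile 21.8) and 0.10 (percentile 98.4, but 96.2 among unmatched lists), T and NK cell markers 0.002 (percentile 34.2) and 0.002 (percentile 50.4), erythroid and megakaryocyte markers -0.04 (percentile 11.1) and -0.02 (percentile 32.8), and mast cell, basophil and eosinophil markers 0.11 (percentile 97.3, but 99.0 after cyclic loess) and 0.008 (percentile 57.3). Between 0 and 4 members of each of these lists reached the floor, and Cd2, Nkg7 and Cpa3 rose over their own lists alone. Only 2 T and NK cell genes and 1 mast cell list gene were tested, so that adjustment corrects for little or nothing. Over all genes tested, limma's adjusted p-values were 0.24 for Cd2, 0.31 for Nkg7 and 0.12 for Cpa3. Limma's genotype test called 0 members of any list of this paragraph over all genes tested.

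**Figure D3:**
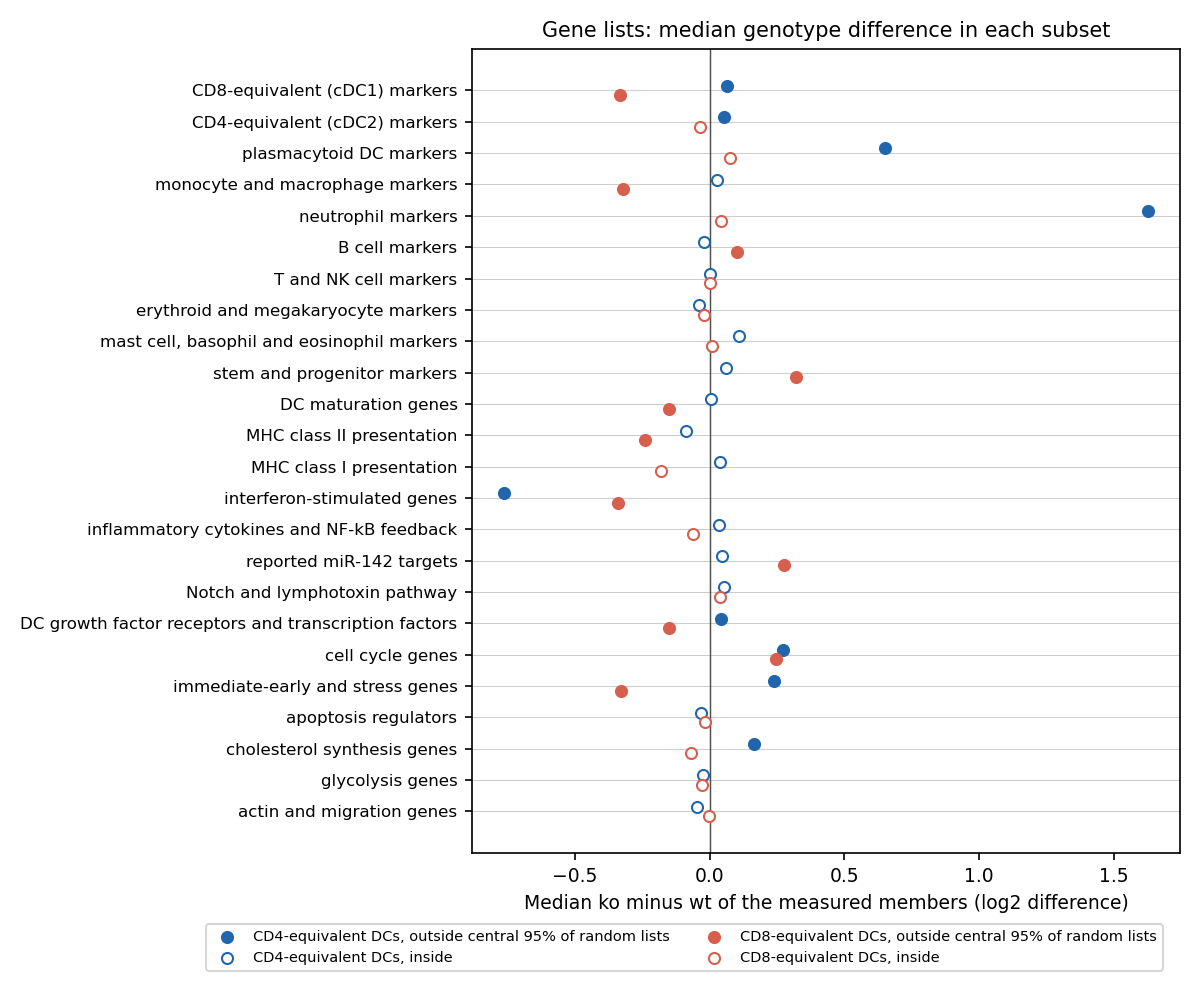
Median log2 difference between ko and wt over the measured members of each gene list, for CD4-equivalent DCs in blue and CD8-equivalent DCs in red, with filled points outside the central 95% of matched random lists. Neutrophil markers reach 1.63 and interferon-stimulated genes -0.76 in CD4-equivalent DCs.

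The genotype difference of some genes was unlike in the subsets, and that interaction, the CD8-equivalent minus the CD4-equivalent genotype difference, could not be tested. The granulocyte genes Lcn2 (3.80 in CD4-equivalent against -0.15 in CD8-equivalent DCs), Ngp (3.86 against 0.10) and S100a8 (3.08 against -0.28) and the macrophage genes C1qb (1.03 against -2.37) and C3ar1 (0.57 against -2.83) had the lowest interaction values. Il18rap (-3.02 against 0.36), Cd209c (-3.25 against -0.36), Ffar2 (-2.72 against -0.39), Drc7 (0.05 against 2.13) and the tetraspanin Cd81 (-0.83 against 1.20) had the highest values. Cd209c and Ffar2 lay below the floor on both CD8-equivalent arrays, where a lower level in ko could not have been seen. Of 10239 genes, 106 had an interaction of at least 1 and 123 of -1 or below.

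The subsets were compared next, first in wt. CD8-equivalent DCs had higher levels of the lymphoid surface marker Ly6d (3.78), the GTP-binding protein Gem (3.70), the adhesion receptor Adgrg1 (3.44), the interleukin-12 subunit Il12a (3.13), Tlr12 (3.12) and Clec9a (3.11), with Pmepa1 (3.24), Atp1b1 (3.22), Mctp2 (3.17) and Gcsam (3.17) also among the highest. The CD8-equivalent minus CD4-equivalent differences were lowest for the C-type lectin genes Clec4n (-4.77), Clec4a3 (-4.74) and Cd209c (-4.56), for F13a1 (-3.99), the mannose receptor Mrc1 (-3.84) and Scel (-3.77), and for the antiviral genes Rtp4 (-4.18), Oas2 (-3.84), Oasl2 (-3.76) and Ddx58 (-3.57). Of 9998 genes compared, 210 were at least 2-fold higher and 314 at least 2-fold lower in CD8-equivalent DCs. Of 21 CD8-equivalent markers, 13 were at least 2-fold higher, with a median of 1.49, and of 20 CD4-equivalent markers, 12 were at least 2-fold lower, with a median of -1.02.

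In ko, the subsets differed in more genes, with 343 of 10118 at least 2-fold higher and 395 at least 2-fold lower in CD8-equivalent DCs. The highest were Drc7 (4.17), Gem (3.70), Il12a (3.67), Dntt (3.57), the cadherin Cdh17 (3.56), Adgrg1 (3.48), the actin-severing Scin (3.46), Ly6d (3.14), Mctp2 (3.09) and the granule protein Nkg7 (2.98). The lowest were Clec4a3 (-6.19), Ms4a6d (-5.00), Clec4a1 (-4.90), Adgre1 (-4.86), the chemokine Ccl9 (-4.84), Lcn2 (-4.78), Mrc1 (-4.53), C3ar1 (-4.45), S100a8 (-4.41) and Ngp (-4.19). CD8-equivalent markers had a median of 0.56, with 9 of 20 at least 2-fold higher and 1 at least 2-fold lower (Cadm1, -1.71), and Clec9a differed by 0.30. CD4-equivalent markers kept 12 of 20 members at least 2-fold lower, with a median of -1.22. Macrophage markers differed in 12 of 13 members at or above the floor, with a median of -1.67 against -0.50 in wt, and neutrophil markers in 9 of 12, with a median of -1.80 against -0.36 in wt. The median of all genes in this comparison was 0.11 as deposited and -0.001 after cyclic loess, which moved the share of higher genes from 46.5% to 33.3%.

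Across both genotypes, limma with Benjamini-Hochberg adjustment called 1467 of 10239 genes for subset, 817 higher and 650 lower in CD8-equivalent DCs, of which 55.7% were higher as deposited and 44.5% after cyclic loess. Gem (mean 3.70 ± 0.12 (SE)), Adgrg1 (3.46), Oasl2 (-3.74) and Ddx58 (-3.57) had an adjusted p of 0.0018, Mrc1 fell by 4.18 (adjusted p = 0.0023), Ly6d rose by 3.46 (adjusted p = 0.0029) and Clec4a3 fell by 5.47 (adjusted p = 0.0038), while Clec9a did not pass (mean 1.70, adjusted p = 0.14). CD8-equivalent markers gave 11 higher members over all genes tested and 15 adjusted over the list alone, and CD4-equivalent markers 14 and 17 lower members, which include the sort markers Sirpa and Itgam. Interferon-stimulated genes were lower in CD8-equivalent DCs, with 18 over all genes tested and 19 adjusted over the list alone, and medians of -1.83 in wt and -1.32 in ko. DC maturation genes fell in 9 and 14 members, with the chemokine Ccl22 at -3.01 in wt and -3.25 in ko. All 25 cell cycle genes at or above the floor were higher in CD8-equivalent DCs in both genotypes, 19 over all genes tested and 25 adjusted over the list alone, with medians of 0.68 in each genotype, and the replication licensing gene Mcm5 stood at 0.82 and 1.03. Plasmacytoid markers gave 6 higher and 2 lower members over all genes and 7 and 3 over the list alone, and macrophage markers 7 and 10 lower members. The subset differences of the genotypes were correlated across genes (Pearson r = 0.79, Spearman correlation 0.72), with 112 genes at least 2-fold higher and 224 at least 2-fold lower in both, where independent lists would share 7.03 and 12.1, and 0 in opposite directions.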

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

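The tests of the granulocyte list in CD8-equivalent DCs, of admixed CD8-equivalent RNA and of plasmacytoid genes were chosen after the results were seen, and the test with further granulocyte genes was written before its values were seen.

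C1qb stood out because its genotype difference ran in opposite directions in the subsets, 1.03 in CD4-equivalent and -2.37 in CD8-equivalent DCs, and this difference was not tested. C1qc ran the same way (0.96 and -1.26), just under 2-fold in CD4-equivalent DCs. Outside the comparisons, among 13610 probe sets without a single gene symbol, 34 were at least 2-fold higher and 7 at least 2-fold lower in ko in both subsets.

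The first pattern was the higher level of granulocyte genes on the ko CD4-equivalent array, where an effect of miR-142 loss that raises them in both subsets alike is argued against by the list's median of 0.041 in CD8-equivalent DCs. Granulocytes or their precursors in the ko sort may be a source, since another list of granulocyte genes had a median of 0.13 at percentile 99.5 of matched random lists, with Slpi, Olfm4 (1.35) and Pglyrp1 (1.08) higher. This evidence is weak: only those 3 of its 12 members at or above the floor passed 2-fold, wt CD8-equivalent DCs already carry Slpi (9.46) and Pglyrp1 (8.47), which are thus not specific to granulocytes here, and the abundant members Anxa1 (-0.50) and Il1r2 (-0.84) were lower in ko. Camp, abundant in granulocyte precursors, stayed at 5.10 below the floor, though Ltf of the first list rose by 1.75 to 6.31. The CD11c gate would remove most granulocytes, and 4 of the 14 markers of the first list also reached the floor in wt DCs. Among those, Mmp8 (8.48 in wt CD4-equivalent DCs) was lower in ko (-0.69). An effect of miR-142 loss on CD4-equivalent DCs alone stays open and was not tested.

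The second pattern was the higher level of some CD8-equivalent and most plasmacytoid genes on the same array. The CD8-equivalent list as a whole was not clearly higher: 5 of 18 members at or above the floor passed 2-fold, 9 lay below 0, and the median over members above the floor was -0.012. Cells like the sorted ko CD8-equivalent DCs, mixed into the sort, are argued against as the whole cause. In a linear mixture the 8 raised genes need shares of 18.2% or more, with a median of 49.5%. That median ranks Cadm1 highest, since its level exceeds the ko CD8-equivalent array itself and no share reaches it. Cadm1 differed by only 0.14 between the subsets in wt, so it says little about admixed CD8-equivalent RNA. The raised genes were left out, and the 10 other genes with the largest CD8-equivalent minus CD4-equivalent differences in wt allow a median of 11.5%. Leaving them out used the ko CD4-equivalent array: Clec9a and Tlr12, among the highest in wt, dropped out, which favours a low median. Of these 10 genes, 7 allow less than 18.2%, among them Gem (7.69%) and Ly6d (11.3%), but Pmepa1 (45.7%) and Atp1b1 (40.6%) leave room for more, and CD8-equivalent precursors that lack the 7 genes were not tested. Plasmacytoid DCs or their precursors cannot be told apart from an effect in the CD4-equivalent cells. The plasmacytoid list lay at percentile 100, and 10 of its 11 members at or above the floor lay above 0, among them Cd300c (0.90) and Tcf4 (0.83). Ly6d (0.14) hardly moved, and Irf7 (-0.26), also a member of the interferon list that fell, was lower. The B220 gate would remove plasmacytoid DCs. Even so, in wt 8 of 12 plasmacytoid markers at or above the floor were at least 2-fold higher in CD8-equivalent than in CD4-equivalent DCs. None of the 12 was 2-fold lower, and the median was 1.18. The gate therefore does not settle the matter, and these markers may not be specific to plasmacytoid DCs here. An effect of miR-142 loss on CD4-equivalent DCs was not tested.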

How the results depend on the processing

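The count without the neutrophil and plasmacytoid lists and the repeat without the CD4-equivalent arrays were chosen after the data were seen. With the stricter floor, which leaves fewer genes, the 2-fold counts were 102 for genotype in CD4-equivalent and 88 in CD8-equivalent DCs, and 241 for subset in wt and 353 in ko. At 1.5-fold they were 768, 807, 1521 and 2046 in that order, and at 3-fold 73, 55, 214 and 249. Repeated normalisation and the mean of a gene's probe sets kept each of these counts within 1.5 times. The genotype calls common to both subsets numbered 17 as reported, 3 without the floor, 141 with the stricter floor, 307 with the trended and robust prior, 242 at an adjusted p of 0.1, 216 after quantile normalisation and 120 after cyclic loess. All 17 genes kept their call in these settings, except that 3 of 17 did without the floor and the stricter floor left 12 of them to test, all called. Subset calls numbered 946 without the floor and 2615 at an adjusted p of 0.1, and the cause of these shifts was not tested. After quantile normalisation 50.2% of the subset calls were higher in CD8-equivalent DCs. The CD8-equivalent list in the CD4-equivalent genotype comparison turned from 0.06 to -0.012 when only members above the floor were used, where the 7 other members no longer counted. Across genes, the correlation of genotype differences ran from 0.44 to 0.58 and that of subset differences from 0.75 to 0.83, and 48 to 51 list medians stood outside the central 95%. Under cyclic loess 364 of the values of named genes kept their side of 2-fold and 11 fell below it, and under quantile normalisation 366 and 9. Without the members of the neutrophil and plasmacytoid lists, 221 genes differed in CD4-equivalent DCs, 126 higher and 95 lower. The repeat without the CD4-equivalent arrays decides nothing, because the called genes were selected for large and alike differences in both subsets. No paired analysis was possible because the labels give no replicate numbers, apart from the additive fit itself, which compares the genotypes within each subset, and leaving out any array leaves that fit no residual degrees of freedom. The planned seed-site search was not run. Signal over background could not be judged without detection calls, so differences involving values below the floor of 5.68 are the least certain.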

Other observations

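The test on Mpo with Elane and Prtn3 was chosen after the result was seen, as were the progenitor genes below. The window test around Mir142 was written before its result was seen, but after genes next to Mir142 were seen to be higher.

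Some genes active in haematopoietic progenitors or fetal haematopoiesis were higher in both ko arrays, picked by hand and without a test of the group. With Hoxa9 (3.46 in CD4-equivalent and 3.02 in CD8-equivalent DCs) went its partner Meis1 (0.95 and 1.70), Eya1 (3.61 and 3.12), Igf2bp3 (1.52 and 1.79), Skida1 (1.17 and 1.66) and Myb (1.11 and 0.94). Meis1 (adjusted p = 0.079), Skida1 (adjusted p = 0.055) and Myb (adjusted p = 0.061) did not pass the genotype test over all genes. Of the same hand-picked genes, Sox4 (-0.11 and 0.97) and Dntt (0.21 and 2.20) were not higher in both subsets. The fixed list of stem and progenitor markers lay inside the central 95% of random lists in CD4-equivalent DCs (median 0.06, percentile 91.6) and above it in CD8-equivalent DCs (0.32, percentile 99.9). The stem and progenitor genes Kit (0.13 and -0.60) and Cd34 (0.22 and -0.09) did not move with them.

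The third pattern was the higher level of genes near Mir142 in both ko arrays. Rnf43 and Mpo, next to Mir142 or near it, and Ppm1e (1.16 and 1.09) were 3 of 20 neighbours that differed by at least 2-fold the same way in both subsets. Windows that overlap the one around Mir142 were left out, and 0 of 18110 windows around other genes, 0% of them, held as many, the highest being 2. The rise of genes next to Mir142 prompted this test, so its outcome was largely fixed beforehand and it cannot decide the cause. An effect of the targeted allele on its neighbours may be a cause. Granulocyte precursors that bring Mpo RNA into both ko sorts cannot be told apart from this: in CD8-equivalent DCs the difference of Mpo exceeded the higher of Elane (0.24) and Prtn3 (0.38) by 2.38, but Elane lay below the floor on both arrays and the wt level of Prtn3 (8.04) would hide a small share. Regulation of Rnf43 by miR-142 itself stays open, since its 3' UTR was not searched for seed matches.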
